A study of Mus musculus with 2 samples.

How the data were processed

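Short RNA libraries from the left cerebral cortex of 2 female B6CASTF1/J mice at 36 days of age were sequenced as microRNA-seq, per the labels. The labels give both mice as separate biological replicates and as separately numbered animals under a single donor code, so each library was taken as 1 animal and n = 2 in 1 group. A label for any treatment or second tissue was not given, and no comparison between groups was made.

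The deposited values used were whole-number read counts per gene for each library, in a table with no header that holds 3 count columns. Per the submitters' README notes, they rest on the mm10 assembly and the GENCODE annotation release M21. No source names the columns, and their values were read as unstranded counts, counts on the gene's strand and counts on the opposite strand, since most assigned reads stand in the second of them and the first leaves out, as ambiguous, the reads over genes that overlap on opposite strands. The aligner, the counter, their settings and the trimming of adapters were not given in the sources used here. The README notes themselves hold no measurement. Each table lists 2202 genes, all of which matched the gene identifiers of the 2207 microRNA genes in the M21 annotation, which gave symbols, coordinates and host genes; the other 5 annotated genes are not analysed here. Each table opens with 4 lines that name no gene and hold the reads that were unmapped, that mapped to several places, that mapped to no annotated gene and that were ambiguous. These were left out of library sizes and tests. In mouse 1 they were 2271144 unmapped (32.1% of 7082096 reads), 2448356 at several places (34.6%) and 432362 in no gene (6.1%), and in mouse 2 they were 1709821 unmapped (27.3% of 6253481 reads), 2327665 at several places (37.2%) and 352119 in no gene (5.63%). No read was ambiguous on the sense strand, while 134651 and 147893 were in the unstranded column.

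These steps limit the values. A read that fits several copies of a hairpin entered no gene count, so the counts of multi-copy microRNAs leave out any such reads, whose number per gene is unknown. The counts are per gene, so the 2 arms of a hairpin cannot be told apart, and reads over genes that overlap on opposite strands are told apart by strand in the sense column but given to neither gene in the unstranded one. The hybrid carries CAST alleles, and reads that differ from the mm10 reference may have been lost, which these tables cannot test. No molecular identifiers were named, so PCR copies count as reads. Every floor, exact test and interval of a log2 ratio covers counting error only, and the interval of Pearson's r treats genes as independent. A count of 0 was taken to allow up to 3 counts, which is 1.55 CPM in mouse 1 and 1.61 CPM in mouse 2.

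From the deposited counts the sense column was used throughout, and CPM was computed over the 1930234 (mouse 1) and 1863876 (mouse 2) sense counts. A gene was called detected at 10 CPM or more in both mice. Tests between the mice ran on the 324 genes at 10 CPM or more on average. Agreement used log2(CPM + 1). edgeR estimated the common biological coefficient of variation with TMM factors (0.983 and 1.02) and an intercept-only design, which leaves a single degree of freedom per gene. Each gene's pair of counts was compared with a two-sided exact binomial test against the TMM library sizes, adjusted by Benjamini-Hochberg over the 324 genes, with a threshold of 0.05 and at least 2-fold. Log2 ratios have 95% Clopper-Pearson intervals. A chi-square of the counts asked whether the libraries were 1 library deposited as 2.

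The 17 gene lists were fixed at the same time as the tests, by family number: neuron-enriched, activity-regulated, let-7, oligodendrocyte, astrocyte and glia, microglia and leukocyte, endothelial and mural, erythroid, choroid plexus and epithelium, muscle, liver with pancreas and pituitary, pluripotency, Hox clusters, mir-17-92 and relatives, Dlk1-Dio3, Sfmbt2, and the mir-183 cluster. The family number kept Mir7-1 and Mir7-2 out of the lists, since their symbols lack the letter. A list's median CPM was placed among 10000 random lists of the same size, and its median log2 ratio, for lists with at least 3 tested members, among 10000 random lists matched on mean CPM through the 20 nearest genes. The genes named were fixed by rule: the 25 with the highest mean CPM, up to 5 members of each list at 100 CPM or more, the members of the erythroid, choroid plexus, muscle and liver lists, and the 10 furthest apart at 100 CPM or more that passed the exact test and 2-fold. Mir124a, Mir9 and all others outside that rule, among them Mir370, Mir26a-2, Mir29c, Mir27a, Mir29b-2 and Mir10b, were named after their values were seen. A host gene is a gene on the same strand that holds the hairpin, protein-coding and named genes first, with the position in it called exon where any annotated exon overlaps. Hairpins were said to share sequence where they have a run of 20 bases in common with another annotated hairpin.

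Alternatives fixed before the data were examined changed the count column, detection threshold, filter, pseudocount (0.5 and 5), scaling (total counts or RLE size factors), fold threshold, list members and left-out replicates. A GC correction, a background of genes with a Mir symbol, shared runs in place of copy suffixes, and the spread without the 10 genes furthest apart were added after the data were seen. Permutation tests used 100000 permutations. On simulated counts for mouse 1 and mouse 2 over 324 genes, the exact test called 99 of 101 genes made 2.5-fold apart (98.0%), 99 of 99 made 4-fold apart and 0 of 124 left equal, with 0 wrong signs. On simulated pairs with a true coefficient of 0.1, 0.3 and 0.5, 5 runs each, edgeR gave 0.101, 0.296 and 0.501. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.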

Results

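MicroRNAs were sequenced from the left cerebral cortex of 2 female mice at 36 days of age. Both animals were of the hybrid strain B6CASTF1/J, and the labels name them as separate biological replicates of a single group. The design therefore implies no comparison between conditions, and the data describe which microRNA genes were read in this tissue and how far the 2 mice differed. Mouse 1 (replicate 1) gave 1930234 sense-strand counts over 2202 microRNA genes and mouse 2 (replicate 2) gave 1863876. Levels are in CPM, the sense counts of a gene scaled to the library's sense total, and each mean ± SD is over n = 2 mice. All counts are reads without stated molecular identifiers, so the floors and the intervals of log2 ratios cover counting error only.

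A few genes held most of the counts, with Mir139, the let-7 genes, Mir127, Mir744 and Mir132 at the top. Reads that mapped to several places entered no gene count, so all ranks and shares cover only reads given to a single gene. Genes that share sequence with another hairpin may therefore rank too low. The 10 most abundant genes took 53.1% ± 2.42 of all sense counts (54.8% in mouse 1 and 51.3% in mouse 2), and the 25 most abundant took 71.3% ± 3.02. In all, 304 genes reached 10 CPM in both mice, 197 reached 100 CPM, 90 reached 1000 CPM and 16 reached 10000 CPM. Of the 304, 300 carried a Mir symbol, and all 1028 genes with another symbol together held 0.0616% of counts. On the mouse mm10 assembly, 70 of the 304 overlapped an exon of another annotated gene on the same strand, 90 lay in no such gene and the rest lay in introns. No count was seen in either mouse for 1480 genes, which allows up to 1.55 CPM in mouse 1 and 1.61 CPM in mouse 2 for each.

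Mir139 (chromosome 7, 101475376 to 101475443, plus strand), in an intron of the phosphodiesterase gene Pde2a, was the most abundant gene at 112269 ± 27908 CPM. It held 254796 counts in mouse 1 and 172474 in mouse 2. Next came Mirlet7g (chromosome 9, 106178840 to 106178927), in an intron of Wdr82, at 71717 ± 9206 CPM, and Mirlet7b (chromosome 15, 85707319 to 85707403), in an exon of the non-coding gene Lncppara, at 69419 ± 28805 CPM. Mir127 (chromosome 12, 109592846 to 109592915), which lay in no annotated host gene, stood at 50032 ± 11142 CPM. Mir744 (chromosome 11, 65734733 to 65734832), in an intron of the kinase gene Map2k4, stood at 48922 ± 9697 CPM. Mir132 (chromosome 11, 75173682 to 75173747), known to be induced by neuronal activity, reached 47377 ± 24725 CPM. Mirlet7i, Mirlet7d, Mirlet7e and Mir99a completed the 10. The next 15 genes were Mir23b, Mir126a, Mir128-1, Mir433, Mir328, Mir151, Mir125a, Mir330, Mir30d, Mir770, Mir487b, Mir652, Mir23a, Mir324 and Mir191, from 19751 CPM for Mir23b down to 8610 CPM for Mir191. Of the 10 highest genes in each mouse, 9 were shared.

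**Figure D1:**
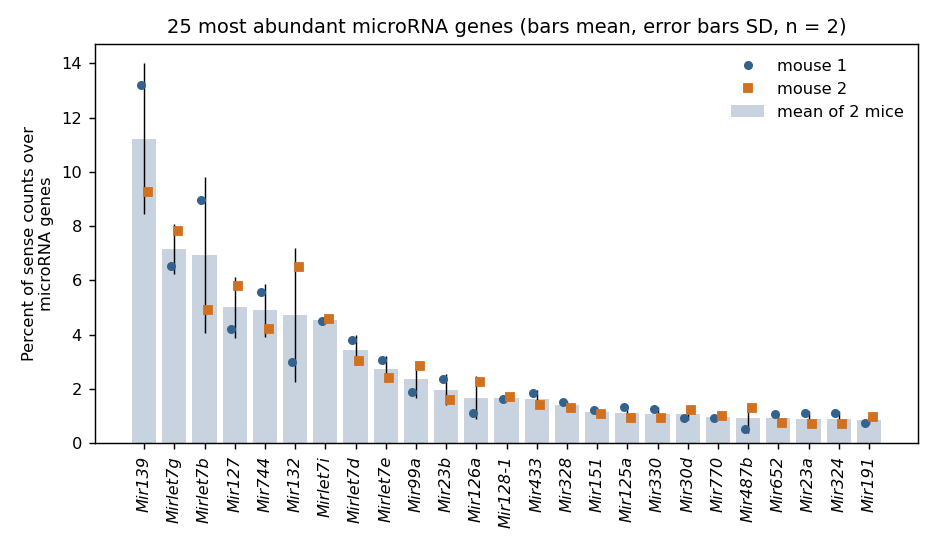
Percent of sense counts over microRNA genes (vertical axis) held by each of the 25 most abundant genes. Bars are means and error bars SDs over n = 2 mice, circles are mouse 1 and squares mouse 2; Mir139 led in both mice, and Mir132 and Mir487b lay more than 2-fold apart.

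Gene lists fixed from background knowledge sorted the counts, and their shares overlap because some genes stand in more than 1 list. These are shares of reads, not of cells, and a member need not be specific to the cell type that names its list. Runs of 20 bases are shared with another hairpin by 6 of 12 let-7, 15 of 35 neuron-enriched, 8 of 15 glia and 6 of 8 oligodendrocyte genes. Reads that fit several hairpins are missing from these shares. The 12 let-7 family genes were all detected and held 25.8% ± 2.83 of counts, led by Mirlet7g, Mirlet7b, Mirlet7i, Mirlet7d and Mirlet7e. Of the 35 neuron-enriched genes, 30 were detected, and they held 24.4% ± 0.0404 of counts. Its leading members after Mir139 and Mir132 were Mir128-1 (16730 ± 633 CPM, chromosome 1, 128202361 to 128202430, intron of R3hdm1), Mir433 (16302 ± 3311 CPM) and Mir770 (9786 ± 563 CPM, exon of the imprinted non-coding gene Meg3). The small SD of the neuron-enriched share covers opposite differences. Mir139 stood at 132003 CPM in mouse 1 and 92535 CPM in mouse 2, and Mir132 at 29894 and 64860 CPM. All 8 genes of the activity-regulated list were detected, at 5.97% ± 2.43 of counts. Most of that share was Mir132, while Mir138-1 (4386 ± 1065 CPM), Mir485 (3267 ± 682 CPM), Mir138-2 (2696 ± 717 CPM) and Mir212 (1147 ± 114 CPM) were lower.

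MicroRNAs of the imprinted Dlk1-Dio3 domain, which are made from the maternal chromosome, formed another large group. In that list 46 of 57 genes were detected, and they held 14.9% ± 1.95 of counts. On chromosome 12, 56 members lay between 109544541 and 109747960, and 1 member lay elsewhere. Mir127, Mir433, Mir770, Mir487b (9162 ± 5516 CPM) and Mir411 (8402 ± 3408 CPM) led the list. In the imprinted Sfmbt2 cluster of chromosome 2 (70 of 78 members between 10466663 and 10518279, 8 elsewhere), 7 of 78 genes were detected, at 0.116% ± 0.00268 of counts. Mir467d (427 ± 129.2 CPM), Mir669c (331 ± 1.49 CPM) and Mir467e (226 ± 80.5 CPM) led it, and 76 of its 78 hairpins share a run of 20 bases with another hairpin, so these levels are uncertain.

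Genes of the glial and vessel lists were also detected. The astrocyte and glia list had 15 of 15 genes detected at 4.33% ± 0.742 of counts, led by Mir125a (11298 ± 2759 CPM), Mir29a (7870 ± 2392 CPM), Mir143 (6755 ± 3330 CPM), Mir26b (6365 ± 141.9 CPM) and Mir30a (5816 ± 1305 CPM). The oligodendrocyte list had 5 of 8 detected at 2.01% ± 0.0663. Mir338 (1972 ± 906 CPM) and Mir219a-2 (1961 ± 771 CPM), both known from myelinating cells, were among them, beside Mir23a, Mir138-1 and Mir138-2, which other cells also express. Mir23a, Mir138-1 and Mir138-2 made up most of that share, at 0.905%, 0.439% and 0.270% of counts. Mir338 held 0.197% and Mir219a-2 0.196%. The endothelial and mural list had 5 of 11 detected at 2.40% ± 1.13 (1.59% in mouse 1 and 3.20% in mouse 2), mostly Mir126a (16828 ± 7851 CPM), which lies in an exon of the endothelial gene Egfl7, and Mir143, which stands in the glia list too, with Mir145a at 272 ± 117 CPM. Counted without regard to strand, where reads over opposite-strand gene pairs are left out, Mir126a, Mir338 and Mir219a-2 had 1 count or fewer, the endothelial and mural share was 0.772%, and Mirlet7e and Mir191 had 0 counts. Of 5 microglia and leukocyte genes 3 were detected at 0.156% ± 0.012, of which Mir150 was the highest at 1397 ± 189 CPM.

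The remaining lists, known from dividing cells and from other tissues, held small shares of the counts. The mir-17-92 cluster and its relatives had 8 of 15 genes detected at 0.324% ± 0.0199, led by Mir93 (1380 ± 156 CPM), Mir17 (584 ± 60.3 CPM), Mir92-1 (547 ± 118 CPM), Mir106b (373 ± 6.997 CPM) and Mir20a (221 ± 5.35 CPM). The choroid plexus and epithelium list had 7 of 13 detected at 0.115% ± 0.0304, with Mir204 at 492 ± 4.71 CPM, Mir34c at 301 ± 295.2 CPM, Mir429 at 117 ± 25.6 CPM and Mir200b at 82.5 ± 65.8 CPM. The 3 erythroid genes held 0.0448% ± 0.0417 (0.0742% in mouse 1 and 0.0153% in mouse 2). The list for liver, pancreas and pituitary had 3 of 8 detected at 0.0298% ± 0.0031, with Mir375 at 210.7 ± 57.4 CPM and the liver microRNA gene Mir122 at 42.9 ± 3.78 CPM. In the muscle list 2 of 10 were detected at 0.00942% ± 0.00361. Mir499 (32.3 ± 12.2 CPM) and Mir206 (31.8 ± 9.28 CPM) led it, and Mir133a-1, Mir133a-2, Mir133b and Mir1a-1 had 0 counts, but the last 4 share runs with other hairpins. The Hox cluster list had 1 of 6 detected at 0.0038% ± 0.00222 (0.00223% in mouse 1 and 0.00537% in mouse 2). The mir-183 cluster list had 2 of 3 at 0.00227% ± 9.31e-05. None of 14 pluripotency genes was detected, and the list held 0.000265% ± 0.000156 of counts (0.000155% in mouse 1 and 0.000376% in mouse 2).

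**Figure D2:**
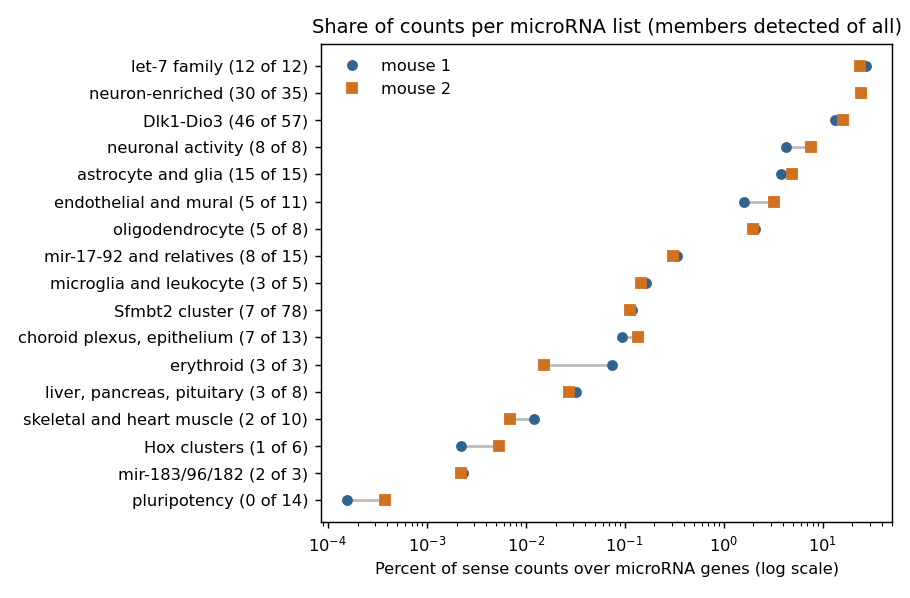
Percent of sense counts over microRNA genes (horizontal log axis) held by each of 17 gene lists, with circles for mouse 1 and squares for mouse 2. Numbers in brackets are members detected at 10 CPM in both mice and all members; the let-7, neuron-enriched and Dlk1-Dio3 lists held the largest shares, and the erythroid list stood apart between the mice.

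As a description of these libraries, the median level of 13 of the 17 lists lay above 95% of random lists of the same size drawn from all 2202 genes. Of those genes, 1480 had no counts in either mouse. Against the 1174 genes with a Mir symbol, a background chosen after the data were seen, 9 lists lay above 95%: neuron-enriched, activity-regulated, let-7, oligodendrocyte, glia, endothelial, choroid plexus, mir-17-92 and Dlk1-Dio3.

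Mir124a and Mir9, the best known neuronal microRNA families, each present in 3 copies, had few counts. Mir124a-1 had 3 counts in mouse 1 and 1 in mouse 2, Mir124a-2 had 1 and 4, and Mir124a-3 had 2 and 3, all close to the floor of 3 counts. Mir9-1 had 35 counts in each mouse, Mir9-2 had 6 and 3, and Mir9-3 had 189 and 131, so that Mir9-1 and Mir9-3 were detected at 10 CPM and the other 4 were not. All 6 of these hairpins share a run of 20 bases with another annotated hairpin. Genes with a copy suffix together held 4.40% ± 0.103 of counts. Their median level was 0 CPM. All other genes also had a median of 0 CPM, and the list lay at the percentile 49.995 of random lists from all genes. Other genes with a Mir symbol had a median of 0.527 CPM, and the list lay at the percentile 0.955 of random lists from these. Of the reads that mapped, 50.9% in mouse 1 and 51.2% in mouse 2 mapped to several places and were given to no gene, so the counts of genes that share sequence leave such reads out.

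**Figure D3:**
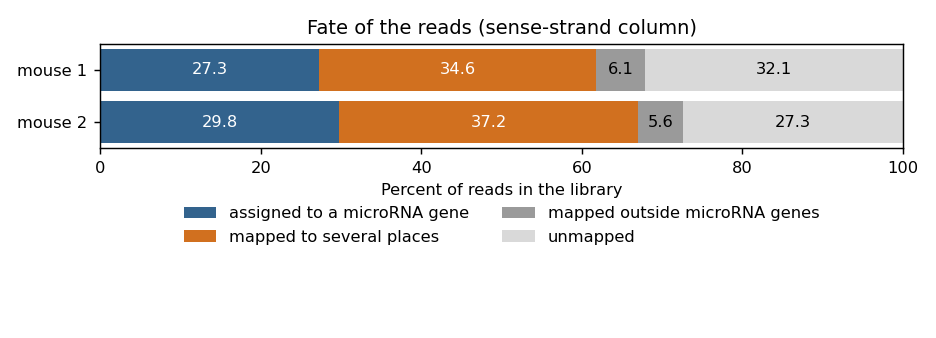
Percent of all reads in each library (horizontal axis) by fate, for mouse 1 and mouse 2. Reads assigned to a microRNA gene made up 27.3% and 29.8%, and reads mapped to several places 34.6% and 37.2%.

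The 2 mice had much the same profile but differed in single genes by more than the counting error of independent reads. Across the 324 genes at 10 CPM or more on average, Pearson's r of log2(CPM + 1) was 0.963 (95% interval 0.954 to 0.970) and Spearman's rho was 0.960. These are correlations across genes, which are not independent replicates, although the interval treats them as such. The chi-square of the counts was 176411 on 721 degrees of freedom (244.7 per degree), far more than sampling noise if all reads are independent. PCR copies, which count as reads here, are not independent. The spread between the mice beyond counting error, as the common biological coefficient of variation of edgeR, was 0.399. Each mouse had 1 library, so here and below differences between animals cannot be told apart from differences of library preparation. The median absolute difference was 0.53 on the log2 scale, or 1.44-fold.

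At least 2-fold apart and past an exact binomial test were 63 of the 324 genes (19.4%), 46 higher in mouse 2 and 17 higher in mouse 1. That test compares 2 libraries for counting error only and says nothing of a condition. With a linear trend of hairpin GC content removed, the split was 38 higher in mouse 2 and 29 higher in mouse 1. Log2 ratios are of mouse 2 over mouse 1, and they and the folds use TMM library sizes, so they differ slightly from ratios of the CPM values. Mir31 (chromosome 4, 88910557 to 88910662) lay furthest apart, 15.5-fold higher in mouse 2 (log2 ratio 3.95, 95% counting interval 3.75 to 4.16), with 112.9 CPM in mouse 1 and 1806 CPM in mouse 2. Mir301 (chromosome 11, 87113004 to 87113089), in an intron of Ska2, was 10.1-fold higher in mouse 1 (log2 ratio −3.34), with 741 and 73 counts. The erythroid Mir451a (chromosome 11, 78073170 to 78073241) was 6.51-fold higher in mouse 1, with 648.6 CPM in mouse 1 and 103.0 CPM in mouse 2. Higher in mouse 2 were Mir26a-1 (7.36-fold), Mir34c (5.35-fold), Mir222 (4.54-fold), Mir21a (4.38-fold, exon of Vmp1), Mir135b (4.16-fold), Mir873a (3.59-fold) and Mir410 (3.45-fold). Of the 25 most abundant genes, Mir132 was 2.10-fold and Mir487b 2.40-fold higher in mouse 2, and the other 23 lay under 2-fold.

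**Figure D4:**
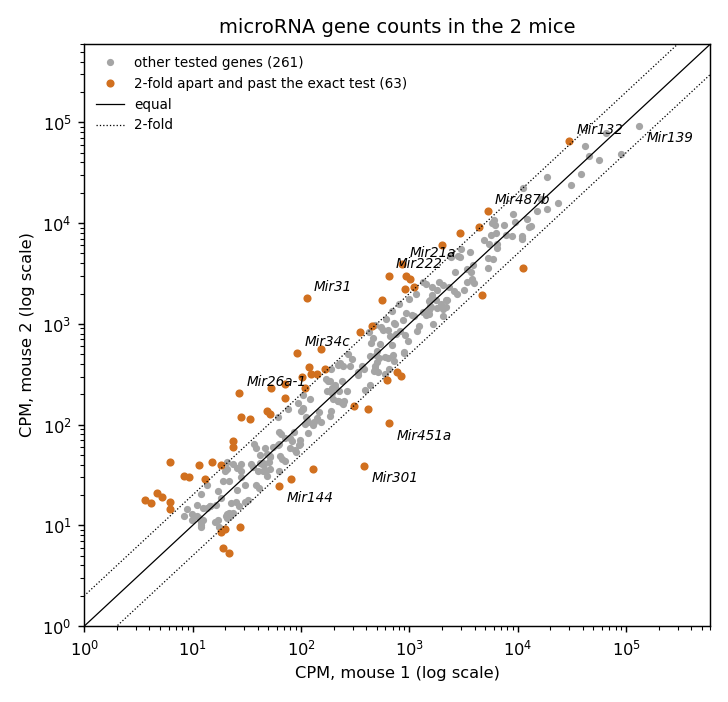
CPM in mouse 1 (horizontal log axis) against CPM in mouse 2 (vertical log axis) for 324 genes at 10 CPM or more on average. Coloured points are the 63 genes at least 2-fold apart and past the exact test, the solid line marks equal levels and the dotted lines 2-fold; Mir31 lay furthest above the line and Mir301 furthest below it.

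By list, the medians of the tested erythroid and muscle genes were lower in mouse 2 than those of matched random lists, with 2 of 3 erythroid and 2 of 4 muscle genes past the exact test and 2-fold. The median log2 ratio of the 3 erythroid genes was −1.40, at the percentile 0.125 of random lists matched on expression, whose central 95% ran from −0.88 to 1.29. Mir451a (−2.70) and Mir144 (−1.40) passed the exact test and 2-fold, and Mir486 (−0.33, adjusted p = 0.334 by the exact test) did not. Mir144 (chromosome 11, 78073005 to 78073070), whose value is the list median, lies beside Mir451a on the same strand. The pair may thus reflect 1 locus, and the random lists were not matched for such closeness, so the percentile may overstate the difference. The median of the 4 muscle genes at 10 CPM or more on average was −1.0, at the percentile 0.62. Mir208a (−1.16) and Mir208b (−1.75) passed, on 38 and 17 counts and on 37 and 11 counts, and Mir499 (−0.84) and Mir206 (−0.65) were under 2-fold. Mir208a (chromosome 14, 54949060 to 54949142, in Myh6) and Mir208b (54975700 to 54975776, in Myh7) lie near each other on the same strand. They need not vary independently, so the muscle percentile may overstate the difference too. The glia list (median 0.58, percentile 97.4) and the endothelial and mural list (0.90, percentile 97.2) lay just inside the central 95%. With total counts the glia list was placed just outside (percentile 97.6). That scaling shifts every log2 ratio by the same amount, so this step came from the random draws alone. The glia list lay inside in the unstranded column (97.0) and without genes that have a copy suffix (93.5, 4 of 9 genes passing). Of the 15 glia genes, 6 passed, all higher in mouse 2: Mir26a-1, Mir21a, Mir26a-2 (2.05), Mir29c (1.58), Mir27a (1.05) and Mir143 (1.00). Of these, Mir26a-1 and Mir26a-2 are copies of 1 microRNA, and they, Mir29c and Mir27a each share a run of 20 bases with another hairpin. With the linear GC trend removed, the glia median was 0.33 (percentile 95.8), with 6 genes higher in mouse 2 and 1, Mir29b-2, higher in mouse 1. Of the 6 endothelial and mural genes, Mir143 and Mir10b (1.75) passed, and Mir126a (0.94) and Mir145a (0.86) were under 2-fold. Mir10a (0.34) and Mir214 (−0.02) did not pass the exact test.

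The remaining lists lay inside the central 95% with TMM scaling and no GC correction. Their medians were 0.18 for 30 neuron-enriched genes, −0.44 for 8 activity-regulated, −0.26 for 12 let-7, 0.45 for 5 oligodendrocyte, 0.06 for 3 microglia and leukocyte, 0.05 for 7 choroid plexus, 0.44 for 4 liver, pancreas and pituitary, −0.09 for 8 mir-17-92, 0.25 for 46 Dlk1-Dio3 and 0.12 for 8 Sfmbt2 genes. Among neuron-enriched genes 7 passed the exact test and 2-fold, all higher in mouse 2. Among Dlk1-Dio3 genes 6 were higher in mouse 2 and 1, Mir370, in mouse 1. Mir376a, Mir136, Mir410 and Mir376b are counted in both lists, so these are not separate observations. With the GC trend removed, the neuron-enriched median was 0.33, outside the central 95% (percentile 98.6), although 4 genes were higher in mouse 2 and 1 in mouse 1, and the Dlk1-Dio3 list 2 and 2. In every list the number past the test and 2-fold was the same adjusted over the list alone as over all 324 genes. With 14 lists tested, chance would put 0.7 outside the central 95%, and 2 were. Of the 5 oligodendrocyte genes, Mir338 (0.93), Mir219a-2 (0.78) and Mir138-1 (0.45) were higher in mouse 2. Mir23a (−0.66) and Mir138-2 (−0.60) were higher in mouse 1, and all 5 lay under 2-fold. Counted without regard to strand, the oligodendrocyte median turned to −0.56 over 3 genes (percentile 3.94). Without genes that have a copy suffix, the median for liver, pancreas and pituitary turned to −0.23 over 3 genes. With the GC trend removed, the medians turned to −0.15 for microglia and leukocyte, −0.06 for choroid plexus and −0.24 for Sfmbt2 genes. In the counts without regard to strand, Mir451a and Mir486 had 0 counts and the erythroid list could not be tested.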

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

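The tests of shared reads, of low expression and of opposite-strand overlap were chosen after the results were seen, while those of GC content, counting error and other cell types were written before their own results were seen, the GC correction among them only after the data had been examined.

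Reads mapped to several places, which enter no gene count, numbered 2448356 in mouse 1 and 2327665 in mouse 2, more than the 1930234 and 1863876 sense counts of all genes together. They need not come from microRNAs, and their origin cannot be read from gene totals. The pattern weighed with them is the low level of Mir124a and Mir9, whose 6 copies held 236 counts in mouse 1 and 177 in mouse 2, most of them in Mir9-3 (189 and 131). If reads shared between copies were the source, other genes with a shared run should read low. In the neuron, activity, let-7, oligodendrocyte, glia and endothelial lists, the 30 members with a run of 20 bases in another hairpin had a median of 277 CPM against 1977 CPM for 44 without (permutation p = 0.0223). That choice of lists came after a first version over all 17 lists (0 against 129.5 CPM, permutation p = 1e-05, the smallest possible), which the 76 sharing genes of the Sfmbt2 list dominated, and without that list alone the medians were 57.3 and 149.7 CPM (permutation p = 0.275), so the test depends on the lists and leaves shared reads open. Whether these 2 families are low in this tissue cannot be judged from the counts, since reads that fit several of their copies entered no gene count. The 20 neuron-list genes without a shared run had a median of 1764 CPM, above all random lists of genes with a Mir symbol. That argues only against a general loss of neuronal microRNAs.

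Counts on the strand opposite to a gene numbered 134716 in mouse 1 (6.98% of the sense counts) and 147964 in mouse 2 (7.94%), above what a count of 0 allows. Reads of a second microRNA gene annotated on the other strand may account for them. In mouse 1, 99.952% of these counts, the lower of the 2 mice, lay in the 64 genes that overlap another microRNA gene on the opposite strand. Only 65 and 71 counts lay elsewhere. Apart from those, the counts equal in number the 134651 and 147893 reads that were ambiguous in the unstranded column, which lie over both genes of such pairs. Such pairs include Mir126a with Mir126b and Mir338 with Mir3065. No biological explanation was tested.

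The 63 genes at least 2-fold apart between mice of the same group are the last pattern, and at most 4 genes lay 2-fold apart in any of 100 Poisson draws at the same means, which excludes nothing, since the genes had been picked by a test against counting error and the draws take PCR copies as independent reads. Hairpin GC content went with the log2 ratio across genes (Spearman rho −0.31, permutation p = 1e-05, the smallest possible; Pearson r −0.24; rho −0.41 at 100 CPM or more), but with the linear trend removed 67 genes passed, 53 of the 63 (84.1%) among them, so a linear GC trend may account for part of the differences and not for most. Of 6 lists for blood, vessels, leukocytes, astrocytes, oligodendrocytes and choroid plexus, 1 lay outside the central 95% of matched random lists. It was the erythroid list, with glia and vessels just inside. The erythroid list holds Mir144 and Mir451a, which lie next to each other on chromosome 11 and need not vary independently. With total counts in place of TMM the glia list was placed just outside (percentile 97.6). That scaling shifts every log2 ratio by the same amount, so this step came from the random draws alone and adds no list. The glia list lay inside without genes that have a copy suffix (percentile 93.5), in the unstranded column (97.0) and with the GC trend removed (95.8). Different shares of other cells in the dissected piece stay open and cannot be told apart from differences between animals. With 1 library per mouse, differences of library preparation cannot be told apart from those between animals either. The design names no difference between these mice, so no biological explanation was tested.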

How the results depend on the processing

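The GC correction, the shared-run definition of copies, the background of genes with a Mir symbol and the spread without the 10 genes furthest apart were chosen after the data were seen. Of the values that answer the main questions, 36 recomputed ones kept within their limits, 11 moved and none reversed. Of the values for single genes and lists, 30 moved, nearly all in the unstranded column, 5 list medians that lay inside the central 95% of matched lists turned sign, 2 became larger and the rest kept. The medians that turned were oligodendrocyte in the unstranded column (−0.56), liver with pancreas and pituitary without copy-suffix genes (−0.23) and, with the GC trend removed, microglia (−0.15), choroid plexus (−0.060) and Sfmbt2 (−0.24); their causes were not tested. Those that became larger were the glia list with total counts (median log2 ratio 0.63) and the neuron list with the GC trend removed (0.33). They then lay outside the central 95% of matched lists. For the glia list this came from the random draws alone, since total counts shift every log2 ratio by the same amount. Pearson's r between the mice was 0.979 with no filter on low counts (722 genes) and 0.933 at 100 CPM or more (207 genes), and the cause was not tested. The share of the 2202 genes called detected was 13.8% at 10 CPM, 22.0% at 1 CPM and 8.95% (197 genes) at 100 CPM. The share of tested genes that differed was 17.4% (36 of 207) at 100 CPM or more, 42.6% at 1.5-fold and 74.7% (242 of 324) with no fold threshold. The coefficient of variation was 0.347 without the 10 genes furthest apart, as their removal implies. A shared run in place of a copy suffix took in 266 genes and 10.7% of counts. In the unstranded column, where reads over opposite-strand pairs are left out, the 10 most abundant genes held 56.5%, 9 lists in place of 13 lay above 95% of random lists, and 1 list (muscle) lay outside the central 95% of matched lists in place of 2. Leaving out a mouse gave 319 or 325 detected genes. With under 100 counts per mouse, the muscle, Hox and pluripotency genes are limited by depth.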

Other observations

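The test of neighbouring genes was set before its result was seen, while the genes named here were chosen after their values were seen.

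Hairpins that lie next to each other and are known to be cut from shared primary transcripts differed between the mice in opposite ways in some places and in like ways in others. Mir23b (chromosome 13, 63300484 to 63300557) was 1.56-fold higher in mouse 1, whereas its neighbour Mir27b (63300712 to 63300784) was 2.04-fold higher in mouse 2. The related pair on chromosome 8 did the same, with Mir23a 1.58-fold higher in mouse 1 and Mir27a 2.06-fold higher in mouse 2. Mir23a, Mir23b and Mir27a each share a run of 20 bases with another hairpin, so reads that fit several places are missing from these counts. The pairs need not be independent. The last member of each cluster, Mir24-1 beside Mir27b (log2 ratio −0.16) and Mir24-2 beside Mir27a (−0.02), did not pass the exact test. With the GC trend removed, the log2 ratio was 0.85 for Mir27b and 1.14 for Mir27a. Both members of the mir-132 cluster were higher in mouse 2, Mir132 by 2.10-fold and Mir212 by 1.11-fold. On chromosome 17, within Spaca6, Mir99b was 3.19-fold higher in mouse 1, Mirlet7e 1.32-fold and Mir125a 1.47-fold. On chromosome X, Mir222 was 4.54-fold and Mir221 1.80-fold higher in mouse 2, and on chromosome 18 Mir143 was 2.00-fold and Mir145a 1.81-fold higher in mouse 2. These folds have counting intervals only.

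A hypothesis was that shared transcription sets the differences between the mice, so that neighbours within 10 kb on a strand would resemble each other. Over 135 genes in 38 clusters (674 pairs), the mean absolute difference in log2 ratio between neighbours was 0.85, against 0.89 for permuted genes (permutation p = 0.311). With the GC trend removed the values were 0.83 and 0.84 (permutation p = 0.467). Without the clusters that hold the Dlk1-Dio3 genes they were 0.86 and 0.95 (permutation p = 0.118), over 87 genes in 35 clusters. Only 77 pairs were then left, so the values over all 674 pairs rest mainly on that domain. The test did not separate neighbours from permuted genes and leaves the hypothesis open, since a p that misses the threshold does not exclude a smaller effect.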
